A study of Homo sapiens with 6 samples.

How the data were processed

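RNA was measured in 6 orthotopic xenograft tumours grown in NOD/Scid mice from clones of MCF7, an established human breast carcinoma cell line of luminal, estrogen receptor-positive type. Per the labels, 3 tumours came from Control clones and 3 from clones made to express Six1, a homeodomain transcription factor. Control clone 1 gave 2 tumours and Control clone 2 gave 1, while Six1 clone 3 gave 2 and Six1 clone 1 gave 1. The labels call tumours of a clone biological replicates, and tumours of one clone share that clone's history.

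The values used are intensity values on a linear scale, deposited by the authors as one number per probe set and array. Per the labels' protocols, RNA was extracted with Trizol and biotin-labelled cRNA was hybridised to 1-colour Affymetrix arrays. MAS5 is named in the submitters' processing notes, and the scaling target and any further step are not given in the sources used here. No column of detection calls was used, so a low intensity could not be told from background array by array. The deposited values ran from 0.95 to 7678 with medians from 39.5 to 41.3, and the 75th percentiles lay within 0.0954 of each other on the log2 scale. This range was inside the tolerance of 0.3 set beforehand, so the deposited scaling was kept. For arrays, the number of tumours limits the precision.

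Of 22277 probe sets, 62 were Affymetrix controls and were left out of the gene tests. In GEO's platform annotation, 19724 probe sets carried 1 gene, 568 carried several and 1923 carried none. Symbols were updated through the Entrez identifier to NCBI RefSeq names (assembly GRCh38.p14, used only for names and for which genes neighbour each other), and 19707 matched. Probe sets with several genes or none were not named. This left SIX1 without a named probe set, so SIX1 is not analysed here and the labels were not checked against the level of the expressed gene. STAT1, STAT2, SERPINE1 and CD24 were likewise without a named probe set.

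Values were turned into log2(value + 16). The 40% of probe sets with the lowest mean were left out, which put the filter at an intensity of 20.6, and for each gene the probe set with the highest mean was kept, leaving 8037 genes. A fold change is on the log2(value + 16) scale and understates the change of genes with low intensity. Of 666 other probe sets of the changed genes above the filter, 609 moved in the same direction, and of the 57 that moved in the opposite direction 1 passed the threshold. Tumours were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 4 residual and 6.55 prior degrees of freedom. Tumours of one clone are not independent clones, so p-values from the fit on tumours measure the spread between tumours and understate the error between clones. Clone as a random block and clone means were run for that reason.

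The 28 gene lists were fixed before the data were examined, and the 24 with at least 5 genes tested were compared with all other genes by limma's camera with a preset correlation of 0.01. Camera with an estimated correlation, fry and the rank form of camera were alternatives. The form with an estimated correlation also tests on the 4 residual degrees of freedom of the fit. Its p can thus rise even where the estimated correlation is low. Fry tests whether a list moves at all and not whether it differs from other genes, so ranges of a list's adjusted p over alternatives leave fry out. Six1 clones were also set against each other, and Control clones against each other, in a fit of 4 clone means. Per-tumour means of stroma lists (fibroblast and matrix, endothelial, leukocyte and macrophage, adipocyte) and 3-prime to 5-prime ratios of the GAPDH and ACTB control probe sets were compared with two-sided exact permutation tests, whose smallest p with 3 against 3 tumours is 0.1.

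Genes named in the text follow a rule set before the data were examined. It takes tested relatives of SIX1 and tested members of the EYA and DACH families, the 15 largest rises and 15 largest falls among changed genes whose groups do not overlap, up to 4 members with the smallest p of each list, and the 5 genes with the smallest p of each clone contrast. ESR1, TFF1, GREB1, PGR, genes that complete a count of 5 or fewer (CDKN1A, RUNX1, PRLR, EGFR, LAMB3, HEY1, NDRG1, RSAD2, SQLE, RPS15 and IER2) and the first and last genes of runs of neighbouring genes were named after their values were seen.

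The fit was tested on simulated data, in 20 draws of 8037 genes of which 200 were changed, for Six1 against Control with 3 against 3 tumours. It recovered 35.1% of genes changed by 0.5 on the log2 scale, 94.0% of those changed by 1 and 100% of those changed by 2, and on average 6.00% of calls were false. Errors in the draws were independent between tumours, while in the data the consensus correlation within clones was 0.346. A far larger share of genes was also called in the data. The share of false calls in the draws thus does not carry over to the data.

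Alternatives covered the scaling between arrays, the pseudocount, the filter, the variance model, clone, the replicate number, array weights, each tumour left out in turn, the handling of several probe sets of a gene, the threshold and the list test. A test without the genes of runs of neighbouring genes was added after the data were seen. Runs were found from medians over 25 neighbouring tested genes, with the genes of the interferon and MHC class I lists left out, and were kept where the median went beyond the largest of 1000 shuffles of the gene order.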

Results

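Expression was measured by array in 6 tumours that grew in the mammary gland of mice injected with MCF7 cells, human breast carcinoma cells of luminal, estrogen receptor-positive type. The design sets 3 tumours of 2 Control clones against 3 tumours of 2 clones that express Six1, a developmental homeodomain transcription factor, and asks which genes differ in tumours with Six1. Each array gave an intensity for 22277 probe sets, with median intensities from 39.5 to 41.3, and 8037 genes were tested. Differences are Six1 minus Control on the log2(intensity + 16) scale, ± SE of the limma fit, with n = 3 tumours per group, and intensities are mean ± SD.

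Of 33 tested genes that interferon induces 32 were higher in Six1 than in Control tumours, and of 18 genes of MHC class I presentation 12 were. In the estrogen response list 18 of 38 tested genes were lower and 2 were higher. As lists, all 3 passed with a preset correlation between genes and none with an estimated one (adjusted p = 0.124, 0.159 and 0.224). In all, 662 genes were higher and 594 were lower in Six1 tumours at a limma adjusted p under 0.05, which is 15.6% of the genes tested. Of these, 171 rose and 92 fell by at least 1 on the log2 scale. The 3 Six1 tumours did not overlap the 3 Control tumours in 1252 of the 1256 changed genes, and in 35.6% of all genes tested. Chance gives 10% if all tumours are independent. Tumours that share a clone raise that share, so 35.6% against 10% overstates the excess. Changed genes were called for these same differences, so their lack of overlap follows in large part from that choice. The count depended on how the shared clones were treated: with clone as a random block 448 genes were higher and 359 lower, and with clone means 350 and 252. It was 605 without Six1 clone 3 replicate 1 and 783 without Six1 clone 3 replicate 2. With quantile normalization the balance turned, to 579 genes higher and 732 lower. Of 112 genes that passed and whose Six1 minus Control difference is printed here, 36 lost their call without some tumour, 31 of them without Six1 clone 3 replicate 1, and all 36 had an adjusted p of at least 0.00942 with every tumour included.

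Genes of the interferon response rose together. Of 33 tested members of that list, 32 were higher in Six1 tumours and none was lower, with a median difference of 1.78, and 33 were higher when adjusted over the list alone. IFI44, an interferon-induced gene, rose from an intensity of 11.7 ± 0.631 to 405 ± 40.1, a difference of 3.92 ± 0.15 (adjusted p = 4.64e-07). IFIT1, which binds viral RNA, rose from 144 ± 22.9 to 1313 ± 135 (3.06 ± 0.14, adjusted p = 8.43e-07). OAS1, a synthetase activated by double-stranded RNA, rose from 161 ± 9.64 to 1181 ± 116 (2.75 ± 0.12, adjusted p = 7.55e-07). IFI44L rose by 3.67 ± 0.21, SAMD9 by 3.13 ± 0.33, XAF1 by 3.11 ± 0.20, OAS2 by 2.96 ± 0.20, IFIT3 by 2.77 ± 0.24 and MX2, an antiviral GTPase, by 2.70 ± 0.21. RSAD2, the remaining member, had a difference of 0.60 ± 0.20 that did not pass (adjusted p = 0.0687). The list median was 1.72 in Six1 clone 1 and 1.80 in Six1 clone 3 against the mean of the Control clones. The list differed from all other genes by camera (adjusted p = 1.65e-36). With an estimated correlation adjusted p = 0.124, and 21 alternatives ran from 3.64e-98 to 0.124.

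Genes of MHC class I antigen presentation were higher as well. Of 18 tested members 12 rose and none fell, with a median difference of 0.70, and 13 were higher when adjusted over the list alone. PSMB9, a subunit of the immunoproteasome, rose from 10.1 ± 3.52 to 266 ± 46.5 (3.43 ± 0.18, adjusted p = 3.37e-06). TAP1, of the transporter that brings peptides to MHC class I, rose by 2.38 ± 0.15, and the class I heavy chains HLA-B and HLA-C by 1.98 ± 0.12 and 1.43 ± 0.08. HLA probe sets can bind RNA of several class I genes, so the share of each is uncertain. The list passed by camera (adjusted p = 5.35e-12), but with an estimated correlation adjusted p = 0.159, the highest of 21 alternatives, of which the lowest was 1.31e-29. Leukocyte and macrophage markers, measured over 16 genes with no intensity filter, had a per-tumour mean of 4.82 ± 0.07 in Control and 4.76 ± 0.05 in Six1 tumours (exact permutation p = 0.2). In both groups 13 of the 16 lay at or below the filter intensity of 20.6, so these markers say little. Of them CD74, the MHC class II invariant chain, was lower in Six1 tumours by limma, at -1.03 ± 0.21 (adjusted p = 0.00791), while AIF1 (0.17 ± 0.20) and CD53 (0.06 ± 0.19) did not pass.

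**Figure D1:**
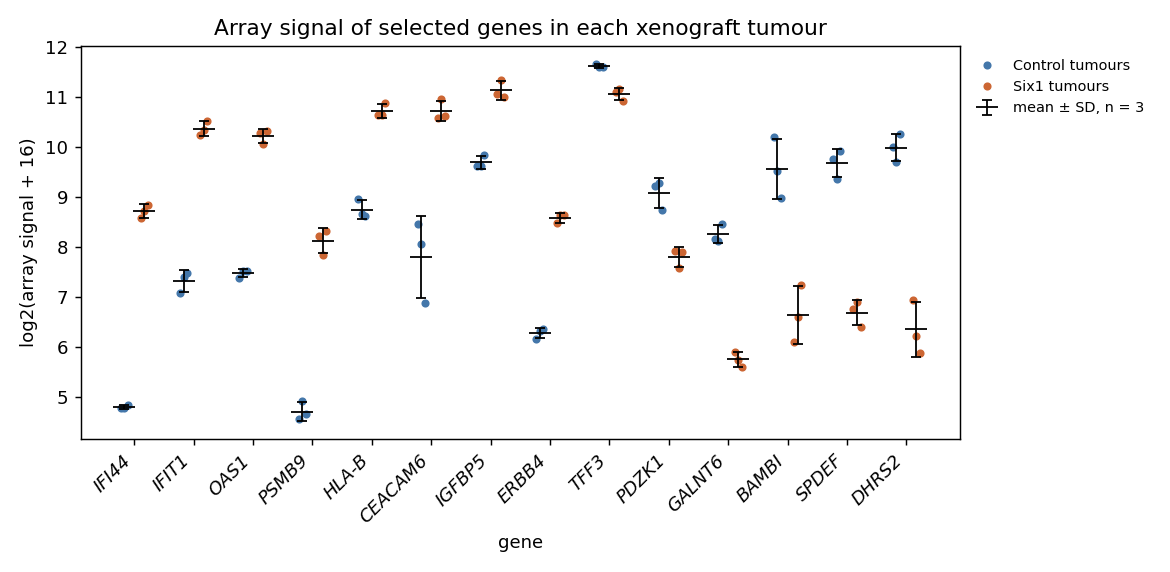
Array signal of 14 named genes in each tumour, as log2(intensity + 16) on the vertical axis, with 3 Control tumours in blue and 3 Six1 tumours in orange, and black bars for the mean ± SD. IFI44 was 3.92 higher and DHRS2 was -3.64, that is lower, in Six1 tumours, and in each gene shown the groups do not overlap.

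Of 38 tested members of the estrogen response list, genes that estrogen receptor alpha induces or that mark its activity, 18 fell and 2 rose, with a median of -0.37, and 18 fell and 4 rose when adjusted over the list alone. PDZK1, a scaffold protein, fell from 532 ± 106 to 207 ± 28.7 (-1.28 ± 0.17, adjusted p = 0.000694). TPD52L1 was at -0.73 ± 0.08 and TFF3, a secreted trefoil peptide, at -0.56 ± 0.07. ESR1, which encodes the receptor itself and was chosen after its values were seen, fell from 2131 ± 218 to 1430 ± 149.8 (-0.57 ± 0.10, adjusted p = 0.00324). TFF1 (0.10 ± 0.04), GREB1 (0.05 ± 0.09) and PGR (0.03 ± 0.19), targets of the receptor that were likewise chosen after their values were seen, did not pass. The members that rose were IGFBP5, a binding protein of insulin-like growth factors, by 1.44 ± 0.11, and THBS1 by 0.46 ± 0.09. The list differed from other genes by camera (adjusted p = 7.35e-06), but with an estimated correlation adjusted p = 0.224, the highest of 21 alternatives, of which the lowest was 3.63e-07. The 22 tested genes of epithelial junctions and keratins had a median of -0.11 and did not pass as a list (adjusted p = 0.122). Their 3 members that fell were KRT18 (-0.27 ± 0.05), PKP3 (-0.67 ± 0.19) and ST14 (-0.54 ± 0.16), and 4 fell when adjusted over the list alone. The calls of PKP3 and ST14 were each lost in 5 of the fits that leave out 1 tumour, with adjusted p up to 0.116 and 0.184. KRT18 kept its call in those fits but lost it in 1 other alternative (adjusted p = 0.127).

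Luminal identity genes moved in both directions. Of 16 tested members 5 fell and 2 rose, with a median of -0.15, and the counts were the same when adjusted over the list alone. SPDEF, an ETS factor of luminal and secretory epithelium, fell from 814 ± 157 to 87.4 ± 17.3 (-3.00 ± 0.18, adjusted p = 5.01e-06), and PRLR, the prolactin receptor, was at -0.87 ± 0.17, beside TFF3, ESR1 and KRT18. ERBB4, a receptor tyrosine kinase, rose from 61.5 ± 5.65 to 369 ± 26.5 (2.31 ± 0.14, adjusted p = 5.01e-06) and AGR2 by 0.33 ± 0.04. The list passed narrowly (adjusted p = 0.0464) and not with an estimated correlation (adjusted p = 0.575), and 12 of 21 alternatives, which ran from 0.00814 to 0.575, ended its call.

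Of 13 tested basal and myoepithelial genes 5 rose and 1 fell, with a median of 0.51, and 6 rose and 1 fell when adjusted over the list alone. CAV1 and CAV2, which encode the coat proteins of caveolae, rose by 1.37 ± 0.21 and 1.04 ± 0.19, and EGFR by 0.86 ± 0.26. These 3 genes lie in runs of neighbouring genes that were higher in Six1 tumours, described below. The others were ITGB4 (0.60 ± 0.15), LAMB3 (0.97 ± 0.24) and OXTR, the oxytocin receptor, which was lower (-0.99 ± 0.19). The list passed by camera (adjusted p = 0.0358), but with an estimated correlation adjusted p = 0.475 and without the genes of the runs adjusted p = 0.259. Over 21 alternatives its adjusted p ran from 0.00206 to 0.475, and 9 ended the call. EGFR, ITGB4 and LAMB3 each lost their calls in 4 of the fits that leave out 1 tumour, with adjusted p up to 0.159, 0.118 and 0.0999.

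Of 18 tested genes of ERK signalling output 4 rose and none fell, with a median of 0.19 and the same counts when adjusted over the list alone. EGR1 and FOS, immediate early transcription factors, rose by 1.31 ± 0.16 and 1.17 ± 0.21, the ephrin receptor EPHA4 by 1.19 ± 0.14 and EPHA2 by 0.82 ± 0.22. EPHA2 lost its call in 4 of the fits that leave out 1 tumour, with adjusted p up to 0.115. EGR1 and FOS also stand in a list of immediate early genes, which dissection and ischaemia can induce. Of the 15 tested members of that list EGR1, FOS, JUNB (0.66 ± 0.17) and IER2 (0.34 ± 0.10) rose and EGR3 fell (-0.81 ± 0.11), 6 rose and 1 fell when adjusted over the list alone, and the list did not pass (adjusted p = 0.122). JUNB and IER2 lost their calls in 3 and 5 of the fits that leave out 1 tumour. The ERK list passed by camera (adjusted p = 0.0217), with adjusted p = 0.380 with an estimated correlation and 0.0649 without Six1 clone 1 replicate 1, in a range from 0.00206 to 0.380.

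Of 13 tested NF-kB and inflammatory genes 4 rose and none fell, with a median of 0.26 and the same counts when adjusted over the list alone. They were LCN2, a secreted iron-siderophore carrier, by 1.82 ± 0.19, TNFAIP3, an inhibitor of NF-kB signalling, by 1.18 ± 0.23, TNFAIP2 by 0.68 ± 0.19 and SOD2 by 0.60 ± 0.15. TNFAIP2 lost its call in each of the 6 fits that leave out 1 tumour and SOD2 in 4, with adjusted p up to 0.102 and 0.112. The list passed by camera (adjusted p = 0.0108), but with an estimated correlation adjusted p = 0.191, and 20 alternatives ran from 0.00301 to 0.191. That estimated correlation, -0.0173, lay below the preset 0.01, so correlation between genes does not account for the lost call. Of 14 tested angiogenic and lymphangiogenic factors FGF13 (1.67 ± 0.25), NRP1 (0.96 ± 0.15) and THBS1 rose and PDGFB fell (-0.76 ± 0.21), with 4 higher and 1 lower when adjusted over the list alone. FGF13 is a fibroblast growth factor homologue that acts inside the cell, THBS1 is known to restrain angiogenesis, and PDGFB, which lost its call in 5 of the fits that leave out 1 tumour, lies in a run of neighbouring genes that were lower. That list had an adjusted p of 0.0457 by camera, 0.257 with an estimated correlation, and lost its call in 11 of 21 alternatives, which ran from 0.0141 to 0.257.

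Of 22 tested p53 targets 5 fell and none rose, with a median of -0.27 and the same counts when adjusted over the list alone. ZMAT3 was at -0.99 ± 0.25, TP53I3 at -0.95 ± 0.24, the proapoptotic BBC3 at -0.51 ± 0.12, the cell cycle inhibitor CDKN1A at -0.47 ± 0.14 and CCNG1 at -0.43 ± 0.12. The list passed by camera (adjusted p = 0.00276), but with an estimated correlation adjusted p = 0.159, and 21 alternatives ran from 0.000847 to 0.159. That estimated correlation, -0.0441, lay below the preset 0.01, so correlation between genes does not account for the lost call. None of the 5 genes kept its call in every fit that leaves out 1 tumour. ZMAT3, TP53I3, BBC3, CCNG1 and CDKN1A lost theirs in 2, 4, 2, 5 and 4 of these fits, with adjusted p up to 0.185. Of 38 ribosomal protein genes RPL3, RPL14, RPL5, RPL19 and RPS15 were lower, from -0.28 ± 0.05 in RPL14 and -0.27 ± 0.05 in RPL3 to -0.18 ± 0.05 in RPS15, with a list median of -0.03 and the same counts when adjusted over the list alone. RPL3 lies in a run of neighbouring genes that were lower, and RPS15 and RPL19 lost their calls in 4 and 1 of the fits that leave out 1 tumour. RPL3, RPL14 and RPL5 kept theirs in those fits but each lost it in 1 other alternative, with adjusted p up to 0.142. The ribosomal list had an adjusted p of 0.0358 by camera and 0.619 with an estimated correlation, lost its call in 9 of 21 alternatives, which ran from 0.00915 to 0.619, and its probe sets can bind RNA of processed pseudogenes.

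**Figure D2:**
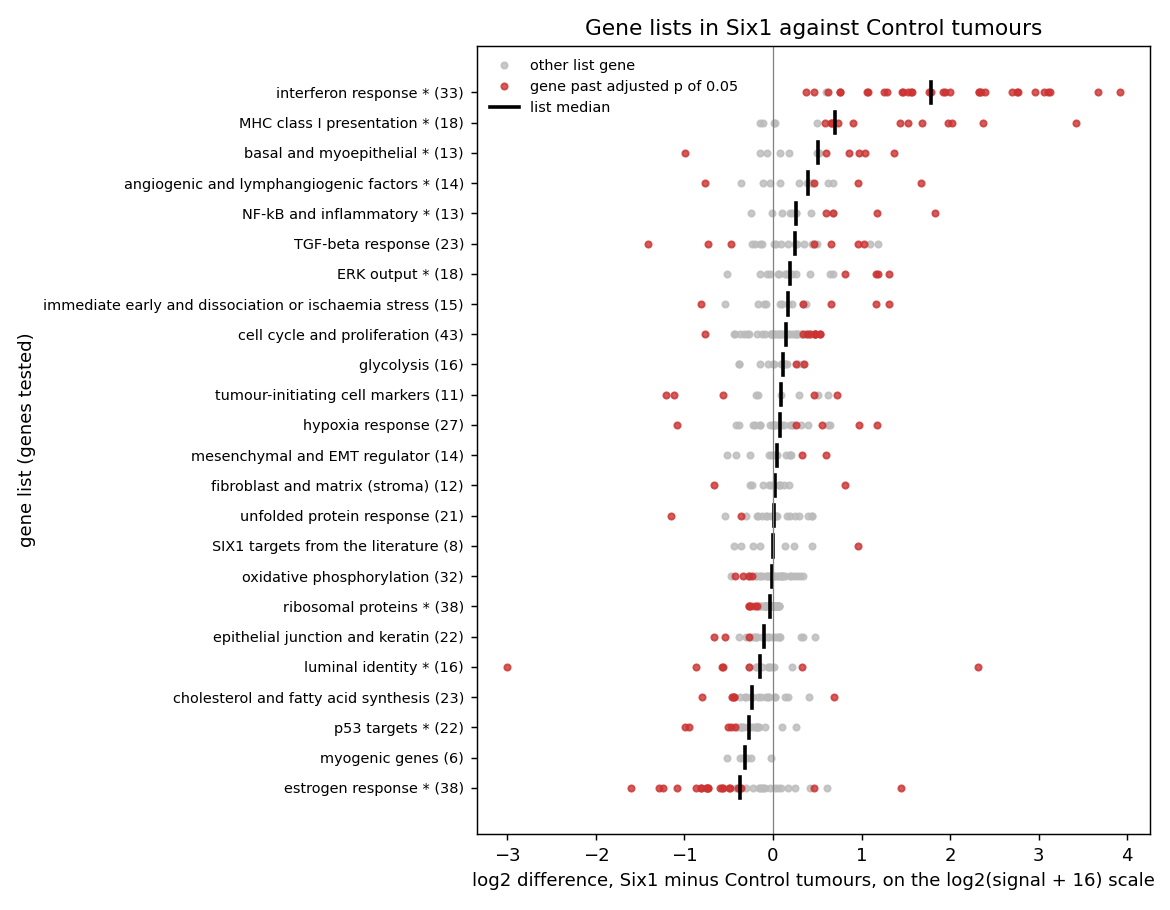
Each point is a tested gene at its log2 difference, Six1 minus Control, on the horizontal axis, with the 24 tested lists and their numbers of genes on the vertical axis, and genes past an adjusted p of 0.05 in red. Black bars are list medians and an asterisk marks lists past an adjusted p of 0.05 by camera with the preset correlation. The interferon response list has the highest median, 1.78, and the estrogen response list the lowest, -0.37.

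Other lists did not pass by camera with the preset correlation. Of 23 tested TGF-beta response genes, SMURF1 (1.02 ± 0.15, in a run of neighbouring genes that were higher), SMAD6 (0.96 ± 0.18), JUNB and THBS1 rose. ID2 (-1.41 ± 0.25), RUNX1 (-0.74 ± 0.19) and CDKN1A fell, and 9 rose and 3 fell when adjusted over the list alone (list adjusted p = 0.122). Of 14 mesenchymal and EMT genes FN1 rose by 0.60 ± 0.10 and ITGB1 by 0.33 ± 0.08, as when adjusted over the list alone, while VIM, which encodes vimentin, was at 0.20 ± 0.12 and did not pass (list adjusted p = 0.533). RUNX1 and ITGB1 lost their calls in 2 fits each that leave out 1 tumour, with adjusted p up to 0.0844. Of 11 tumour-initiating cell markers NOTCH1 (-1.21 ± 0.19), CD44 (-1.12 ± 0.29) and BMI1 (-0.56 ± 0.12) fell and HEY1 (0.72 ± 0.20) and KLF4 (0.46 ± 0.13) rose, with 3 lower and 4 higher when adjusted over the list alone (list adjusted p = 0.955). CD44, KLF4 and HEY1 lost their calls in 4, 4 and 5 of the fits that leave out 1 tumour, with adjusted p up to 0.102, 0.160 and 0.150. The median of that list was 0.10 and its mean -0.05. Of 43 cell cycle genes 8 rose, RRM2 by 0.54 ± 0.08, PTTG1 by 0.47 ± 0.10 and MCM7, which lies in a run of neighbouring genes that were higher, by 0.48 ± 0.08. MYBL2 fell (-0.76 ± 0.13), and 11 rose and 4 fell when adjusted over the list alone (list adjusted p = 0.0809).

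Of 27 hypoxia genes NDRG1 (1.17 ± 0.26), EGLN3 (0.97 ± 0.21), PLOD2 (0.55 ± 0.11) and ALDOA (0.26 ± 0.05) rose and STC2, which is also in the estrogen response list, fell (-1.08 ± 0.19), with 6 higher and 1 lower when adjusted over the list alone (list adjusted p = 0.122). Of 16 glycolysis genes ALDOA and PFKP (0.36 ± 0.09) rose, as when adjusted over the list alone (list adjusted p = 0.132). Of 32 oxidative phosphorylation genes SDHC (-0.43 ± 0.10), ATP5F1A (-0.33 ± 0.07), ATP5PB (-0.28 ± 0.06) and ATP5PO (-0.23 ± 0.07) fell, with 2 higher and 8 lower when adjusted over the list alone (list adjusted p = 0.428). Of 23 cholesterol and fatty acid synthesis genes FASN (-0.80 ± 0.18), SC5D (-0.46 ± 0.13), INSIG1 (-0.44 ± 0.12) and SQLE (-0.44 ± 0.13) fell and CYP51A1 rose by 0.69 ± 0.12, with 2 higher and 6 lower when adjusted over the list alone (list adjusted p = 0.0839). SC5D and INSIG1 lost their calls in 5 of the fits that leave out 1 tumour, SQLE in 4 and FASN in 1, with adjusted p up to 0.159, 0.101, 0.136 and 0.0530. ATP5PO lost its call in 5 such fits, PFKP in 4, SDHC in 2, and NDRG1, EGLN3, ALDOA and ATP5PB in 1 each, with adjusted p up to 0.175. FASN and CYP51A1 lie in runs of neighbouring genes that moved the same way. Of 21 unfolded protein response genes TRIB3 (-1.16 ± 0.18) and ATF4 (-0.36 ± 0.08) fell, both in runs of neighbouring genes that were lower, as when adjusted over the list alone (list adjusted p = 0.785). None of 6 tested myogenic genes passed, on either adjustment (list adjusted p = 0.122). With an estimated correlation no list passed, and the smallest adjusted p was 0.124.

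SIX1 itself is not analysed here, for lack of a named probe set. SIX2 (0.46 ± 0.21, adjusted p = 0.175), EYA2, a cofactor of SIX1 (0.49 ± 0.23, adjusted p = 0.175), and DACH1 (-0.67 ± 0.24, adjusted p = 0.0840) did not pass, on either adjustment. Of 8 tested targets of SIX1 from the literature, SLC12A2, a sodium-potassium-chloride cotransporter, rose by 0.96 ± 0.14 (adjusted p = 0.00155), as when adjusted over the list alone. CDC25A (-0.44 ± 0.17), VEGFC (0.44 ± 0.19) and TGFBR2 (-0.36 ± 0.19) did not pass, and that list, with a median of -0.01 and a mean of 0.08, did not either (adjusted p = 0.755).

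Among the largest rises outside these lists were ATRNL1 (3.01 ± 0.14, from 37.0 ± 5.54 to 410 ± 13.8), DMP1, a matrix protein of mineralised tissue (2.86 ± 0.23), and WIPF1, an actin regulator (2.84 ± 0.19). The cell surface adhesion proteins CEACAM6 and CEACAM5 rose by 2.92 ± 0.32 and 2.72 ± 0.48, and their related sequences leave the share of each uncertain. CEACAM5 lost its call in 1 alternative (adjusted p = 0.0581). On the log2(intensity + 16) scale, which holds back changes that end at low intensities, the largest fall was DHRS2, a short-chain dehydrogenase, from 1013 ± 196 to 69.4 ± 33.7 (-3.64 ± 0.25, adjusted p = 8.86e-06). BAMBI, a decoy receptor of the TGF-beta family, fell from 788 ± 338 to 89.0 ± 42.0 (-2.93 ± 0.32, adjusted p = 0.000230). GALNT6, an enzyme of mucin-type O-glycosylation, was at -2.51 ± 0.16, the signalling adaptor CARD9 at -2.63 ± 0.25, the collagen chaperone FKBP10 at -2.50 ± 0.21, ALDH3B2 at -2.46 ± 0.23 and ANXA6 at -2.41 ± 0.21. EFHD1 (-2.11 ± 0.30), PLAC1 (-2.07 ± 0.27), COL21A1 (-1.94 ± 0.31), PLAT, the tissue plasminogen activator (-1.94 ± 0.23), and PTGES, a prostaglandin E synthase (-1.80 ± 0.31), were lower too. PLCB4 (-2.60 ± 0.20) and SYNGR1 (-1.71 ± 0.18) were among the largest falls and lie in runs of neighbouring genes that were lower. CARD9, FKBP10, PLAC1 and PLCB4 ended at 7.63 ± 3.88, 6.23 ± 3.55, 7.80 ± 0.576 and 9.26 ± 5.93 in Six1 tumours, below the filter intensity of 20.6, so their folds are not known well. The same holds for OXTR, NOTCH1 and CD74, and for DMP1, SAMD9, IFI44, IFI44L, PSMB9, TNFAIP2 and HEY1, which lay below it in Control tumours.

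Differences of neighbouring genes went together. Over 7705 pairs of neighbours the differences correlated at r = 0.187 across genes, which are not independent replicates, while the largest of 1000 shuffles of the gene order gave 0.0339. Between the Control clones r was 0.103 against at most 0.0325 in shuffles, and between the Six1 clones 0.0377 against 0.0305. The largest median over 25 genes was 0.695 between Six1 and Control tumours, beyond the 0.438 of the shuffles, but not beyond them between the Control clones (0.386 against 0.444) or the Six1 clones (0.248 against 0.367). In 8 runs of neighbours, found after this result was seen, medians over 25 genes went beyond those of the shuffles. The 8 runs held 439 genes, 5.50% of those placed, and 182 of the 1212 placed genes that changed, or 15.02%. Runs were picked for these same differences, so the higher share of changed genes follows from that choice. The longest, from GTF2I to WASL, held 147 tested genes with a median of 0.49, of which 124 were higher and 80 passed as higher. Its median was 0.46 in Six1 clone 1 and 0.52 in Six1 clone 3 against the Control clones. Runs from PDE1C to CCT6A (49 genes, median 0.44) and from ACOT13 to BTN2A1 (25 genes, 0.45) were also higher. Most genes of the run from ACOT13 to BTN2A1 are histone genes, which are related to each other. Most of its 8 genes that passed as higher are not histone genes. Runs from RHOT2 to CCNF (35 genes, -0.44), USP36 to QTGAL (46, -0.46), SOX12 to FLRT3 (40, -0.43), HMGXB4 to ADSL (53, -0.44) and EP300 to MAPK11 (44, -0.41) were lower. In the lower runs the Control clones also differed, with medians of clone 1 minus clone 2 of -0.26, -0.33, -0.11, -0.18 and -0.27 in the same order. In the 3 higher runs that difference was -0.09 (GTF2I to WASL), -0.01 (PDE1C to CCT6A) and 0.06 (ACOT13 to BTN2A1). Between the Six1 clones the medians of clone 1 minus clone 3 ran from -0.05 to 0.10 over the 8 runs. Without the genes of these runs 527 genes were higher and 492 lower.

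**Figure D3:**
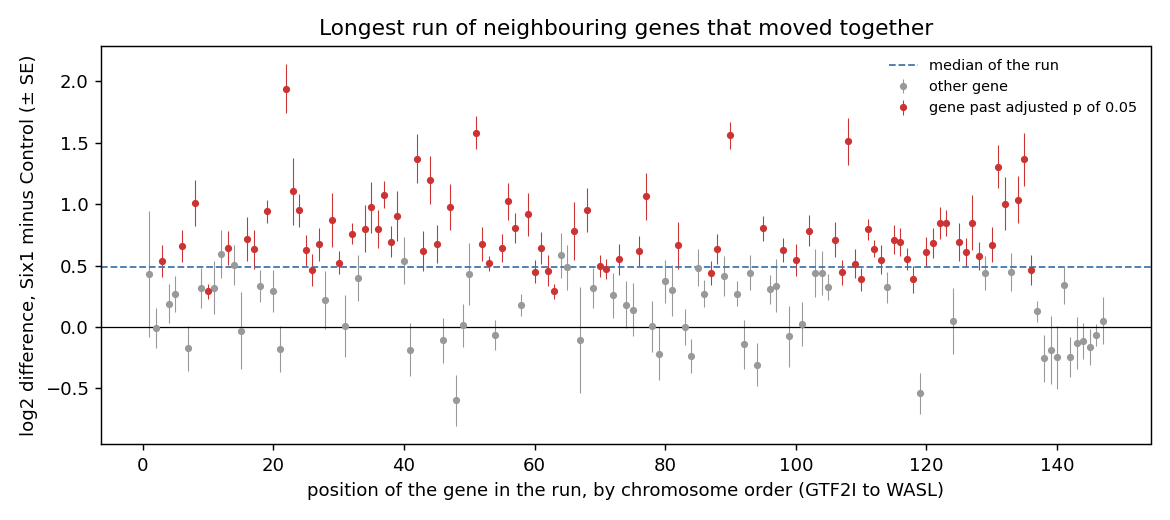
Log2 difference, Six1 minus Control, ± SE on the vertical axis for the 147 tested genes of the longest run, in chromosome order from GTF2I to WASL on the horizontal axis, with genes past an adjusted p of 0.05 in red. The dashed line is the median, 0.49, and 124 of the 147 points lie above 0.

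Clones of one condition were set against each other to see how far clones alike in Six1 status differ. Between Control clone 1 and Control clone 2 limma called 0 of 8037 genes, with 1483 at an unadjusted p under 0.05 and a smallest adjusted p of 0.136. Between Six1 clone 1 and Six1 clone 3 it also called 0 genes, with 716 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0534. The median size of the log2 difference was 0.217 between Control clones, 0.155 between Six1 clones and 0.216 between Six1 and Control tumours, and 71, 92 and 274 genes differed by 1 or more. Control clone 2 and Six1 clone 1 are 1 tumour each, so a difference between clones cannot be told from one between tumours, and sizes from 1 against 2 tumours hold more noise than those from 3 against 3. The fit of clone means had 2 residual degrees of freedom, so 0 calls do not show that clones of a condition are alike. The smallest p between Control clones belonged to NDUFS7 (1.45 ± 0.18, clone 1 minus clone 2), OTUB1 (-1.03 ± 0.13), ISG15 (-0.64 ± 0.09), UCP2 (-0.78 ± 0.11) and CEACAM6 (1.39 ± 0.20). Between Six1 clones it belonged to RNFT1 (-1.48 ± 0.15, clone 1 minus clone 3), EXOC5 (-2.05 ± 0.22), GTF2I, the first gene of the longest run (-2.19 ± 0.24), SGPP1 (-1.56 ± 0.18) and ABCC4 (-1.47 ± 0.18). The first principal component held 59.2% of the variance, with Control tumours between -26.2 and -15.5 and Six1 tumours between 16.8 and 21.97. Across genes, arrays of one clone correlated at 0.985 and 0.989, arrays of other clones of the same group from 0.972 to 0.984, and arrays of different groups from 0.938 to 0.960.

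List means of stroma markers differed between the groups by less than the SD within the Control tumours. The per-tumour mean of 20 fibroblast and matrix genes was 6.17 ± 0.19 in Control and 6.21 ± 0.06 in Six1 tumours on the log2 scale (exact permutation p = 0.9), though COL3A1 was higher (0.82 ± 0.19) and COL5A1 lower (-0.67 ± 0.19) by limma, calls lost in 2 and 4 of the fits that leave out 1 tumour. The fibroblast list did not pass by camera (adjusted p = 0.871). Endothelial markers, with EMCN at -0.16 ± 0.18 and PECAM1 at 0.18 ± 0.27, had means of 4.83 ± 0.11 and 4.77 ± 0.02 (exact permutation p = 0.5). Only 2 of these 16 markers passed the intensity filter, so their means say little. Adipocyte markers had means of 4.96 ± 0.11 and 5.01 ± 0.05 (exact permutation p = 0.5), with CFD lower (-1.22 ± 0.22) and CIDEC at 0.18 ± 0.18. The other adipocyte markers lay below the filter and were not tested, and among them PPARG differed by 1.29, with mean intensities of 5.60 and 37.8, and FABP4 by 0.65, so the mean holds changes in both directions. Mouse RNA binds human probes only in part, so these values bound the stroma loosely. The log2 ratio of 3-prime to 5-prime signal was 0.87 ± 0.50 in Control and 0.59 ± 0.60 in Six1 tumours for ACTB (exact permutation p = 0.5) and 0.22 ± 0.17 and 0.10 ± 0.06 for GAPDH (exact permutation p = 0.4).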

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

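Among probe sets without a single named gene, which the gene comparisons leave out, 131 of the 1182 above the intensity filter passed a limma adjusted p of 0.05 between Six1 and Control tumours when every probe set was tested on its own, 62 higher and 69 lower. They are listed because they form a signal in data outside the gene comparisons. Of all 13329 probe sets tested in this way 1525 passed, a share close to theirs, so these probe sets did not change more often than others.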

How the results depend on the processing

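Each alternative changed one choice, and the test without the genes of runs of neighbouring genes was chosen after the data were seen. Of the 112 genes past the threshold whose Six1 minus Control difference the report prints, and of the lists past it, none changed direction under any alternative that was run on them. Alternatives on the handling of several probe sets of a gene gave counts of genes only, so directions were not followed there. Genes named only as ends of runs or for differences between clones were not followed through the alternatives. The 1256 changed genes became 807 with clone as a random block, 359 of them lower, and 602 with clone means, 350 higher and 252 lower. All 807 and 601 of the 602 were among the 1256. Array weights, from 0.386 for Control clone 2 replicate 1 to 2.63 for Six1 clone 3 replicate 1, gave 1901, with 997 higher and 904 lower. An adjusted p under 0.1 gave 911 lower genes, and a log2 change of at least 1 as well left 263, with 171 higher and 92 lower. Fits that leave out 1 tumour gave from 605 genes (353 higher, 252 lower, without Six1 clone 3 replicate 1) to 1251 (702 higher, 549 lower, without Control clone 1 replicate 1), and 783 without Six1 clone 3 replicate 2. Quantile normalization turned the split to 579 higher and 732 lower. Without the genes of the runs 1019 genes passed. Other alternatives stayed within 1.5 times of 1256. Clone means and fits that leave out 1 tumour compare fewer samples. The fits that leave out 1 tumour are alike in that, yet ran from 605 to 1251 genes, so the number of samples alone does not explain them. The cause of these changes was not tested.

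The 10 lists past the threshold became 6 with robust variance, 6 with clone as a random block and 0 with an estimated correlation, and 7 without the genes of the runs. Among alternatives other than fry, the interferon, MHC class I, estrogen response, p53 and NF-kB lists lost their call in 1 alternative each, that with an estimated correlation, and the ERK list in 2. The estimated correlation of the p53, NF-kB and angiogenic lists (-0.0441, -0.0173 and 0.00935) was below the preset 0.01. Correlation between genes thus does not account for the calls these lists lost there. Luminal identity lost it in 12 of 21, angiogenic factors in 11, and basal genes and ribosomal proteins in 9 each. Fry, which tests whether a list moves and not whether it differs from other genes, passed 10 lists, with TGF-beta response, cell cycle and myogenic genes among them and luminal, basal and ribosomal genes not. Of the lists not past the threshold, epithelial, cell cycle, hypoxia, glycolysis and cholesterol genes passed it in some alternative of camera, in the same direction. The medians of the SIX1 target, mesenchymal, tumour-initiating, oxidative phosphorylation, unfolded protein and fibroblast lists, none past the threshold in any alternative, changed sign in some. Between Six1 clones 3 genes passed with quantile normalization, 3 with a pseudocount of 1 and 5 with a pseudocount of 64, against 0, and the cause was not tested. Between Control clones 0 passed in every alternative run.

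Of the same 112 genes, 66 kept their call under every alternative that tested them and 76 in every fit that leaves out 1 tumour. KRT18, CEACAM5, AGR2, RPL3, RPL14, RPL5, CD74, PTTG1, ATF4 and ATP5F1A kept it in all of those fits but lost it in 1 other alternative each. Calls lost were at most 31 in a fit without 1 tumour (without Six1 clone 3 replicate 1), 28 with clone means, 27 without an intensity trend and 20 with clone as a random block. Replicate numbers restart within each clone and pair nothing across groups. With the replicate block 1018 genes passed, 554 higher and 464 lower. The planned result on SIX1 probe sets was not run, since no probe set was named SIX1. Without detection calls, genes near the filter at an intensity of 20.6 cannot be told from background, which limits the folds of low genes.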

Other observations

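The tests of DNA copy number were fixed before their results were seen, and the other tests in this part were chosen after the results they bear on were seen. The per-tumour mean of the interferon list varied little within a group, at 7.16 ± 0.13 (SD, n = 3) in Control and 9.06 ± 0.10 (SD, n = 3) in Six1 tumours on the log2 scale. ISG15, a member of that list, was among the genes with the smallest p between Control clones, with intensities of 1139 in clone 1 and 1785 in clone 2 against 3960 and 3891 in the Six1 clones.

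Of 33 interferon response genes 32 rose and of 18 MHC class I genes 12, though as lists neither passed with an estimated correlation (adjusted p = 0.124 and 0.159). For the interferon list, scaling between arrays is argued against by its median, which was at least 1.774 under 3 scalings, and RNA quality by a group difference of 1.91 ± 0.11 with the ACTB ratio as a covariate. The RNA quality test was not run on the MHC class I list. Over 21 alternatives, with quantile normalization and a common median among them, the median of the MHC class I list ran from 0.631 to 0.803. This argues against scaling for that list as well. DNA copy number of the genes themselves is argued against by their 170 nearest tested neighbours, whose median difference was 0.02356 (bootstrap SE 0.0272) where the 51 list genes had 1.53, with 60 neighbours of MHC class I genes at 0.04. Leukocytes in the Six1 tumours stay open: their 16 markers had a median difference of -0.01584, but 13 lay at or below the filter intensity in both groups, and mouse RNA binds human probes only in part. Six1 and other traits that the Six1 clones share stay open too, and were not tested.

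In the estrogen response list 18 of 38 tested genes fell, 2 rose and 18 did not pass, and the list's call was lost with an estimated correlation (adjusted p = 0.224). On a lower share of tumour cells the test cannot decide. The epithelial list's median lay 0.2684 above that of the estrogen response list, only a little beyond 2 times its bootstrap SE of 0.121. That SE takes genes as independent and is too small. The estimated correlation between genes was 0.185 in the epithelial and 0.0836 in the estrogen response list. RNA quality is argued against by a group difference of -0.3101 ± 0.04 with the ACTB ratio as a covariate. A lower share of tumour cells stays open. Whether lower ESR1 may belong to Six1 or to traits of the clones stays open too, since 2 clones per arm do not separate these.

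Part of the gene changes followed gene order. Disjoint pairs of clones set a Six1 clone against one Control clone and the other Six1 clone against the other Control clone. Their differences correlated at 0.5468 and 0.676 across genes. These values argue against differences that arose separately in each clone as the only source of the changes. They do not exclude such differences in part of the genes. DNA copy number differences between the cell lines had the values they need, with neighbours correlated at 0.1866 against at most 0.0339 in 1000 shuffles and a highest window median of 0.695 against 0.438. Shuffles of the gene order break every pattern that neighbours share. These values therefore do not tell copy number from other causes that act on neighbouring genes. Neighbours also correlated beyond shuffles between the Control clones (0.103) and between the Six1 clones (0.0377), though their largest window medians did not go beyond shuffles (0.386 against 0.444 and 0.248 against 0.367). Over the 8 runs the Control clones differed by medians from -0.33 to 0.06. A candidate explanation is that clones gained or lost stretches of chromosome, which would put part of the difference outside Six1, and whether clones of an arm share such changes by origin stays open. No DNA was measured. The runs found hold 15.02% of the placed genes that changed, so most changed genes lie outside these runs. Runs were kept only where a window median went beyond the largest of 1000 shuffles, so weaker or shorter runs can be missed. The 15.02% thus sets no upper limit on the share of changes that copy number could explain.

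With 3 against 3 tumours, 10 splits are too few for a share under 0.05. The real split gave 1256 genes and the highest of the others 0, with 1 split of 10 as large. For lists, the real split gave 10 past the threshold by camera with the preset correlation and the highest of the others 9, with 1 split of 10 as large, so under that setting splits that mix the conditions also called many lists. Each other split leaves the conditions unequal between its sides, so part of their difference remains in it. That difference also widens the spread within a side, which lowers the count of genes. The other splits thus do not show what chance alone gives.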
